A study of Mus musculus with 6 samples.

How the data were processed

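Livers of Fah-deficient mice were profiled on 6 Affymetrix whole-transcript mouse gene arrays, 3 from mice on continuous NTBC and 3 from mice after 7 days without it. Per the labels' protocols, 100 ng of total RNA was amplified with the GeneChip Whole Transcript PLUS kit and hybridised as biotin-labelled material. The deposited table holds one normalized intensity per probe set and array on a linear scale. Per the submitters' processing notes, Transcriptome Analysis Console was used, and its version, the background correction and the normalization method were not given in the sources used here. All intensities (100%) lay within 0.006 of 2 to the power of a number with 2 decimals, itself rounded to 2 decimals, so the authors' values had been rounded on the log2 scale and turned back. Array minima lay between 3.58 and 3.89 and maxima between 20738 and 22227. Median log2 signals were 5.29, 5.44 and 5.43 on continuous replicates 1 to 3 and 5.26, 5.21 and 5.39 on withdrawal replicates 1 to 3. The interquartile range ran from 2.39 to 2.62 in the continuous group and from 2.53 to 2.78 in the withdrawal group. The table carries no detection or background flags, so a low signal is not a statement that a transcript was absent, and a fold from a low signal can be compressed. The number of arrays, 3 per group, limits the precision.

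Genes were named from the platform's annotation, in which 23521 probe sets have 1 gene symbol, 1814 have several and 9137 have none here. No gene was named from a probe set with several symbols. Of the symbols, 23328 matched a mouse gene table (GRCm38.p6) by identifier and 0 changed. The genome build of the array design was not given in the sources used here, so no coordinates are printed. For 1082 genes with more than 1 probe set, the one with the highest mean over the 6 arrays was used. Transcripts of near-identical family members, such as those of Cyp2a, Cyp2c, Gstm, Mup and histone genes, can bind the same probes. Values of the table were taken as normalized and were not normalized again. Pearson correlations across probe sets were 0.978 to 0.980 within the continuous group, 0.985 to 0.991 within the withdrawal group and 0.955 to 0.969 between groups. Probe sets are not independent replicates. Between 0.748% and 1.80% of probe sets had identical deposited intensities, with no tolerance, in any pair of arrays, so no array was a copy of another.

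Log2 intensities of all 34472 probe sets were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with the default prior, 4 residual and 10.2 total degrees of freedom). The contrast was withdrawal minus continuous NTBC, two-sided, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. No filter on low signals was applied. Gene lists, 31 in number with 451 of 510 members measured, were tested with camera at a preset correlation of 0.01, adjusted over the 31 lists. Of the 12 lists that passed, none passed with a correlation estimated per list. Fry was run beside camera. It tests whether the genes of a list move one way on balance and compares them with no other genes. Beside each count of members over all probe sets stands the count adjusted over the list alone.

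The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 10 largest rises and 10 largest falls among probe sets past the threshold with 1 symbol and fully separated groups. Predicted genes and pseudogenes were passed over, which left out 1 among the rises and 0 among the falls. From each list the 3 members with the smallest p-values could be named, and Fah and Hpd always. Other members of a list were named where 5 or fewer passed in a direction, or as well-known members of a list, and were chosen after their values were seen. These were Abcb4, Adipoq, Akr1b8, Alb, Atf4, Bhlhe40, Cpa1, Cpt1a, Cyp7a1, Ebp, Fabp1, Gldc, Gpx2, Igfbp1, Mcm2, Me1, Mki67, Osgin1, Sqle, Stard4, Top2a and Trib3.

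The alternatives were quantile normalization or median centring on top of the deposited values, leaving out dim probe sets, the replicate number as a block, limma's array weights, probe sets with 1 symbol only, eBayes with trend and robust, each array left out in turn, 2-fold thresholds, camera with an estimated correlation, fry, and the mean of a gene's probe sets. Folds were also computed with each signal below the lower quartile of its array raised to that quartile, which stands in for a background level that is not given. The fit was tested on simulated data with the real means and spreads of these 34472 probe sets. It recovered 44% of 100 probe sets with a true log2 change of 1 and 92% of 100 with a change of 2, with 0 wrong signs and 5 false calls. No other probe sets were changed in it, whereas 9.40% of the real ones passed. The Benjamini-Hochberg cutoff depends on that share. These recovery rates are therefore not the share of real changes of such sizes that was found. In simulated lists of 20 members, camera called 5 of 5 lists shifted by 1 and 0 of the unshifted ones. The simulated genes were drawn independently of each other. Members of the real lists vary together, with estimated correlations of 0.239 for NRF2 targets and 0.311 for p53 targets. The simulation therefore does not show how often camera at the preset correlation calls such lists falsely.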

Results

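Liver RNA was measured in male mice of the C57Bl/6J background that carry a point mutation in Fah, the gene of fumarylacetoacetate hydrolase, which catalyses the last step of tyrosine breakdown. Loss of this enzyme is the defect of hereditary tyrosinemia. NTBC (nitisinone) blocks the pathway at an earlier step, at the enzyme encoded by Hpd. In the continuous group (3 arrays) NTBC was given throughout at 8 mg/l in drinking water, and in the withdrawal group (3 arrays) it was stopped at 11 weeks of age for 7 days. All livers were taken at 12 weeks. The labels list dextrose at 3% for all 6 arrays, which leaves open whether it continued during the withdrawal. Each array gave normalized signals for 34472 probe sets, and values below are log2 signals as mean ± SD over the 3 arrays of a group. The comparison asked which liver transcripts differ after a short interruption of NTBC. The labels call the replicates biological without naming animals, so the p-values measure the spread between these samples.

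After NTBC withdrawal, targets of NRF2 and p53 were higher, and male-biased liver genes, bile acid genes, amino acid catabolic genes and acute phase genes were lower. These 6 lists passed camera, and with an estimated correlation they gave adjusted p from 0.104 to 0.340. Slc7a11, the cystine/glutamate exchanger, rose 111-fold on the probe set with the higher signal (3.99 ± 0.46 to 10.78 ± 0.29) and 13.5-fold on a separate one (3.63 ± 0.24 to 7.38 ± 0.46). Hsd3b5, a male-biased steroid dehydrogenase of the liver, fell from 9.87 ± 0.36 to 3.25 ± 0.78, a 98.1-fold difference in signal. Its withdrawal signals of 4.09, 2.54 and 3.12 lay near or below the lower quartiles of those arrays (4.03 to 4.16), and no background level is given, so the size of these folds is uncertain. With signals under the lower quartile of their array raised to it, the folds were 54.7 for Hsd3b5 and 86.8 and 9.04 for Slc7a11. Cdkn1a, the cell cycle inhibitor p21, was 15.5-fold higher, and Afp, the fetal serum protein, was 10.0-fold higher. Alb, the main serum protein of hepatocytes, had a log2 change of -0.05 (SE 0.14, adjusted p = 0.867).

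In all, 3241 probe sets (9.40% of those tested) passed limma's adjusted p of 0.05, of which 2139 were higher and 1102 lower after withdrawal. At least a 2-fold change was met by 748 of the higher and 430 of the lower ones. Of 31 gene lists 12 passed camera, 5 upward and 7 downward, and 0 passed with an estimated correlation. Among probe sets with 1 gene symbol, 1764 were higher and 782 lower. The higher share was 66.0% as deposited and 77.2% once each array was centred on its median, which moved the median change of all probe sets from -0.08 to 0.02. With quantile normalization it was 58.3% (1890 higher and 1351 lower), with a median change of -0.02. The count was 1454 without withdrawal replicate 1, 1795 without withdrawal replicate 2 and 2078 without continuous replicate 2. The 3 arrays of one group lay wholly above those of the other for 9499 probe sets (27.6%), where chance gives 10%. This separation held for each gene described below as higher or lower. The first principal component took 56.9% of the variance, with scores from -54.7 to -27.7 in the continuous group and from 30.0 to 48.3 in the withdrawal group.

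Fah carries its mutation in both groups, and its signal was 7.82 ± 0.42 with NTBC and 7.66 ± 0.23 after withdrawal (log2 change -0.15, SE 0.22, adjusted p = 0.718). Hpd, the target of NTBC, was lower after withdrawal, at 12.02 ± 0.06 against 12.66 ± 0.14 (log2 change -0.64, SE 0.15, adjusted p = 0.0211). Of 7 measured genes of phenylalanine and tyrosine catabolism, 4 fell and none rose (4 lower adjusted over the list alone), with a median change of -0.64. The other 3 that fell were Got1 (-1.77), an aspartate aminotransferase, Tat (-1.23), the first enzyme of tyrosine breakdown, and Hgd (-0.77), the enzyme after Hpd. The list passed camera (adjusted p = 0.00456) but not with an estimated correlation (adjusted p = 0.498). Without withdrawal replicate 1 the list count was 2 lower, with adjusted p = 0.0656 for Hgd and 0.0854 for Hpd. The Hpd call was also lost without continuous replicate 3 (adjusted p = 0.0710), withdrawal replicate 2 (0.0775) and withdrawal replicate 3 (0.0629), and after median centring (0.0706).

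Among heme synthesis genes, Alas1, the rate-limiting enzyme, rose 2.82-fold (10.26 ± 0.19 to 11.76 ± 0.06, adjusted p = 2.53e-04). Of 7 measured, Alas1 alone passed (1 higher and 1 lower adjusted over the list alone). Cpox and Ppox had changes of -0.55 (adjusted p = 0.0987) and -0.56 (adjusted p = 0.162). The list median was -0.23 and its mean 0.04, and camera gave a downward direction with adjusted p = 0.957.

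NRF2 targets, genes of glutathione synthesis, detoxification and NADPH supply, rose with few exceptions. Of 26 measured members, 23 rose and none fell (23 higher and 1 lower adjusted over the list alone), with a median change of 2.05. Beside Slc7a11 the members with the smallest p-values were Abcc4, an export pump for organic anions (19.3-fold, adjusted p = 1.35e-06), and Pgd of the pentose phosphate pathway (8.67-fold). Cbr3, a carbonyl reductase, rose 49.6-fold, from 4.81 ± 0.70 to 10.45 ± 0.18. Hmox1, which degrades heme, rose 14.5-fold, from 6.71 ± 0.52 to 10.57 ± 0.23. Gpx2 (-0.50), Osgin1 (0.34) and Akr1b8 (-0.05) did not pass. The list gave camera adjusted p = 5.09e-32, and adjusted p = 0.104 with an estimated correlation. The count of 23 was the same without any 1 array.

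p53 targets rose as well, with 14 of 21 measured members higher and none lower (16 higher adjusted over the list alone) and a median change of 1.22. Cdkn1a went from 6.46 ± 0.48 to 10.41 ± 0.14 (adjusted p = 8.27e-06). The death receptor Tnfrsf10b rose by 2.67 (SE 0.16) and Eda2r, another receptor of the same family, by 2.57 (SE 0.17). The camera test gave adjusted p = 5.98e-14, and adjusted p = 0.249 with an estimated correlation. On the same arrays sinusoidal endothelial markers had a median change of 0.38, with 3 of 14 measured past the threshold. Camera with an estimated correlation gave them adjusted p = 0.340. The hepatocyte list had a median of -0.07.

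The cell cycle list did not pass camera. Of 27 measured cell cycle genes, 3 rose and 1 fell (the same counts adjusted over the list alone), with a median of 0.003 and camera adjusted p = 0.300. Those that rose were the replication genes Pcna (1.29, SE 0.14), Mcm6 (0.98, SE 0.20) and Mcm2 (0.77), and Tk1, which supplies thymidine nucleotides, fell (-0.86). Mki67 and Top2a, which mark dividing cells, had changes of -0.11 and -0.22 and did not pass. Without withdrawal replicate 1, or without withdrawal replicate 2, 1 gene was higher. Without continuous replicate 1 the lower count was 2. The Mcm6 call was lost without continuous replicate 2 (adjusted p = 0.0540), withdrawal replicate 1 (0.0705) and withdrawal replicate 2 (0.0526), and that of Mcm2 without continuous replicate 3 or any 1 withdrawal array (highest adjusted p = 0.0892).

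Integrated stress response genes rose in part, with 9 of 23 measured members higher and none lower (10 higher adjusted over the list alone). Sesn2, a stress-induced inhibitor of mTORC1, rose 3.47-fold, the transcription factor Atf3 3.38-fold, and Slc3a2, the heavy chain that pairs with Slc7a11, 2.49-fold. Atf4, the central transcription factor of this response, had a change of -0.11 and Trib3, one of its targets, of -0.04, and neither passed. The list median was 0.07 and its mean 0.49. For this list camera gave adjusted p = 0.00476, adjusted p = 0.340 with an estimated correlation, and adjusted p = 0.137 without dim probe sets. Of 19 measured ER chaperone and unfolded protein response genes, 1 rose and 2 fell (the same counts adjusted over the list alone), with a median of 0.14 and camera adjusted p = 0.457. Dnajb9, an ER cochaperone, rose by 1.71 (SE 0.28), while Derl3 (-1.03) and Herpud1 (-0.92), both of ER-associated degradation, fell. The Herpud1 call was lost without withdrawal replicate 1 (adjusted p = 0.0517), where the lower count of the list was 1.

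**Figure D1:**
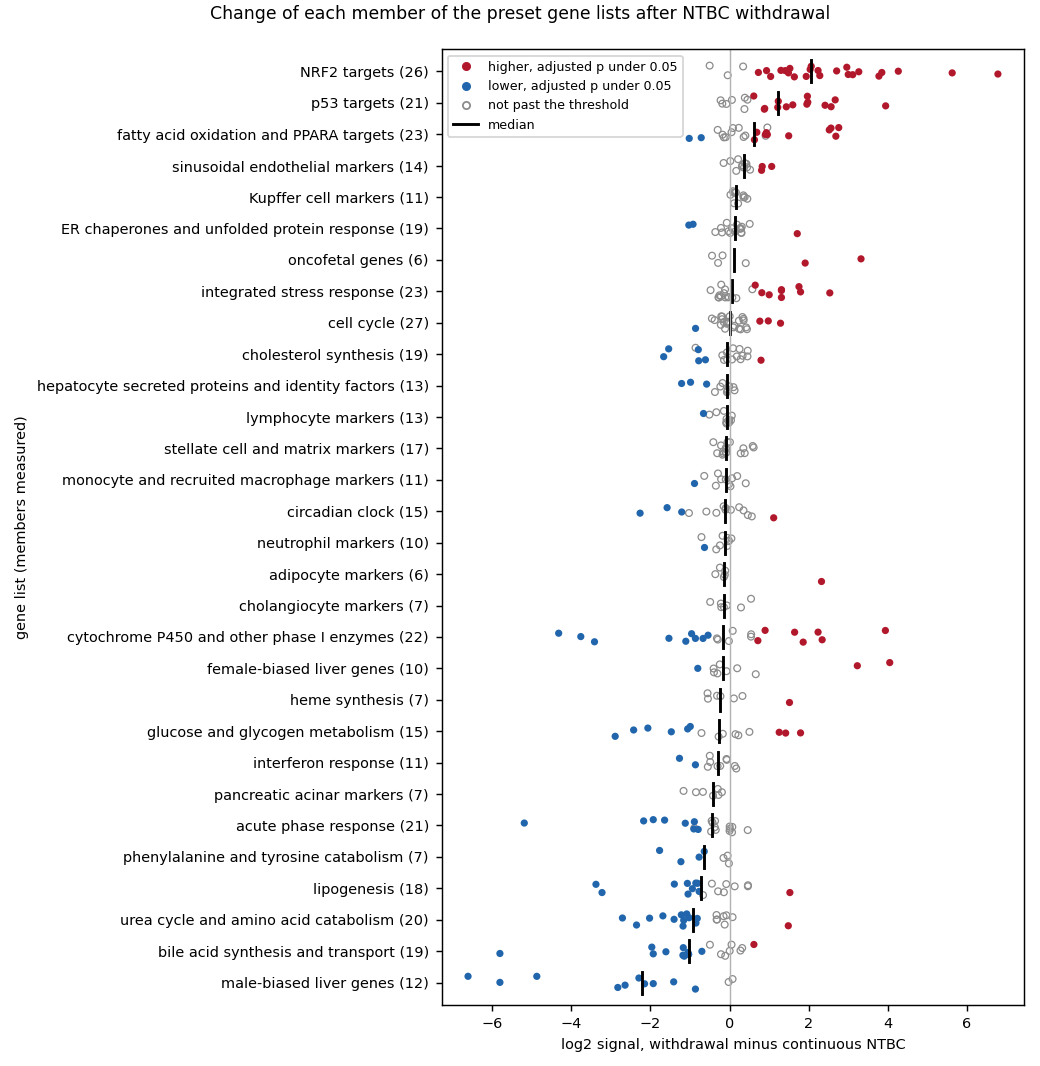
Log2 change of signal (withdrawal minus continuous NTBC, horizontal axis) for each measured member of 30 gene lists (vertical axis, members measured in parentheses). Filled points passed an adjusted p of 0.05, open points did not, and black bars mark list medians, which run from -2.22 for male-biased liver genes to 2.05 for NRF2 targets.

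Male-biased liver genes had the lowest median of the 31 lists. Of 12 measured members, 10 fell and none rose (10 lower adjusted over the list alone), with a median change of -2.22. Slco1a1, an organic anion uptake carrier, went from 11.38 ± 0.24 to 5.57 ± 0.28 (56.1-fold lower, adjusted p = 5.85e-07). Elovl3, a fatty acid elongase, was 29.4-fold lower and C6, a terminal complement component, 7.09-fold lower. Camera gave adjusted p = 1.10e-14, and adjusted p = 0.104 with an estimated correlation. Slco1a1 and Cyp7b1 are also on the bile acid list and Cyp2d9 on the cytochrome P450 list.

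Female-biased liver genes went both ways, with 2 of 10 measured members higher and 1 lower (the same counts adjusted over the list alone). Cyp2a4 rose from 9.40 ± 0.09 to 13.45 ± 0.01 (16.6-fold). Cyp2b9 rose from 4.14 ± 0.35 to 7.37 ± 2.02, with 8.89, 8.14 and 5.08 on the 3 withdrawal arrays. Its log2 change was 3.23, but 2.47 without withdrawal replicate 1, 4.38 without withdrawal replicate 3 and 4.11 with array weights. Cyp2c69 fell (-0.80). The list median was -0.16, its mean 0.59 and camera's direction upward (adjusted p = 0.563). The Cyp2b9 call was lost without continuous replicate 2 (adjusted p = 0.0796), continuous replicate 3 (0.0690), withdrawal replicate 1 (0.0746) or withdrawal replicate 2 (0.0983), and in each case 1 member was higher. Limma's trend and robust options also ended it (0.0810). The Cyp2c69 call held among these left-out arrays without continuous replicate 3 only, and the highest adjusted p was 0.126, without withdrawal replicate 2. It was also lost with quantile normalization (0.0751) and median centring (0.0993).

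Cytochrome P450 and other phase I enzymes went in opposite directions within the list. Of 22 measured, 7 rose and 9 fell (9 higher and 9 lower adjusted over the list alone), with a median of -0.16 and camera adjusted p = 0.453. Cyp2c54 went from 10.66 ± 0.15 to 6.33 ± 0.22 (log2 change -4.32, SE 0.17), Cyp2c50 was 13.6-fold lower and Cyp2c37 10.7-fold lower. Cyp2a5, a coumarin hydroxylase, was 15.4-fold higher. The Cyp2a and Cyp2c families hold near-identical genes whose transcripts could share probes, so values of single members are uncertain. The counts were 4 higher and 6 lower without withdrawal replicate 1, and 4 higher and 7 lower without withdrawal replicate 2.

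Bile acid genes fell, with 11 of 19 measured members lower and 1 higher (12 lower and 1 higher adjusted over the list alone) and a median change of -1.04. Besides Slco1a1, the uptake carrier Slco1b2 fell by 1.97 (SE 0.15) and Cyp7b1, of the alternative synthesis pathway, fell by 1.93 (SE 0.16). Cyp7a1, the rate-limiting enzyme of the classical pathway, had a change of -1.17. Abcb4, the canalicular phospholipid flippase, was the member that rose (0.62). The Abcb4 call was lost without continuous replicate 3, withdrawal replicate 1 or withdrawal replicate 2, which left 0 higher members (highest adjusted p = 0.112). The camera test gave adjusted p = 2.98e-07, and adjusted p = 0.249 with an estimated correlation.

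Genes of the urea cycle and amino acid catabolism fell as well. Of 20 measured, 12 fell and 1 rose (the same counts adjusted over the list alone), with a median change of -0.94. Oat, ornithine aminotransferase, was 5.11-fold lower, Hal, which deaminates histidine, 6.54-fold lower and Prodh, proline dehydrogenase, 3.22-fold lower. Gldc, of the glycine cleavage system, rose (1.49). For this list camera gave adjusted p = 1.12e-08, and adjusted p = 0.303 with an estimated correlation.

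Lipogenic genes fell, with 9 of 18 measured lower and 1 higher (10 lower and 3 higher adjusted over the list alone) and a median change of -0.72. Thrsp, a lipogenic regulator, was 10.4-fold lower and Scd1, the main hepatic stearoyl-CoA desaturase, 9.36-fold lower (12.53 ± 0.39 to 9.30 ± 0.54). Pklr, liver pyruvate kinase, fell by 1.40. Me1, malic enzyme, which is also on the NRF2 list, was the member that rose (1.53). Camera gave adjusted p = 1.04e-04, and adjusted p = 0.388 with an estimated correlation. Without continuous replicate 1 the counts were 2 higher and 8 lower.

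Of 23 measured genes of fatty acid oxidation and PPARA targets, 10 rose, 2 fell and 11 did not pass (14 higher and 2 lower adjusted over the list alone), with a median of 0.63. Those with the smallest p-values, Cd36 (2.69, SE 0.27), a fatty acid uptake receptor, Acot2 (2.57, SE 0.28), a thioesterase, and Vnn1 (2.52, SE 0.29), a pantetheinase, are not enzymes of beta-oxidation itself. The 2 that fell were Cpt1a (-0.72), which admits fatty acids to mitochondria, and Fabp1 (-1.02), which binds them in the cytosol. The list gave camera adjusted p = 1.43e-04, adjusted p = 0.498 with an estimated correlation, and adjusted p = 0.0509 with fry. Without continuous replicate 2 or withdrawal replicate 1 the counts were 6 higher and 1 lower, and without continuous replicate 3 or withdrawal replicate 3 they were 9 higher and 1 lower. The Cpt1a call was lost in those 4 cases (highest adjusted p = 0.0588) and with median centring (0.0616). Cidec, a lipid droplet protein that is not on the list, rose 14.9-fold (5.49 ± 0.19 to 9.39 ± 0.39).

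Of 19 measured genes of cholesterol synthesis, 5 fell and 1 rose (6 lower and 3 higher adjusted over the list alone), with a median of -0.06 and camera adjusted p = 0.366. The sterol enzymes Nsdhl (-1.67), Tm7sf2 (-1.54), Sc5d (-0.78) and Ebp (-0.79) and the sterol carrier Stard4 (-0.61) fell, and Sqle, squalene epoxidase, rose (0.80). The Sqle call held, among left-out arrays, without continuous replicate 2 only, and was lost with quantile normalization (adjusted p = 0.0827). The lower count of the list was 3 without continuous replicate 1, continuous replicate 2, withdrawal replicate 1 or withdrawal replicate 3, 4 without withdrawal replicate 2 and 6 without continuous replicate 3. The cholesterol synthesis list passed camera without continuous replicate 3 (adjusted p = 0.0145) and with quantile normalization (adjusted p = 0.0376). Ebp was lost without continuous replicate 1, continuous replicate 2, withdrawal replicate 1 or withdrawal replicate 3 (highest adjusted p = 0.0857). Stard4 was lost in the same cases and without withdrawal replicate 2 (highest adjusted p = 0.164), and both were lost with median centring.

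Glucose and glycogen genes changed in both directions, with 6 of 15 measured lower and 3 higher (7 lower and 4 higher adjusted over the list alone), a median of -0.28 and camera adjusted p = 0.199. Slc2a2, the hepatocyte glucose transporter, was 7.43-fold lower (10.27 ± 0.23 to 7.38 ± 0.25). Ugp2, which makes UDP-glucose, rose 3.47-fold and Ppp1r3c, a glycogen-targeting phosphatase subunit, 2.39-fold. Igfbp1, a secreted IGF-binding protein, was the other member that rose (1.42). Its call was lost without continuous replicate 2 (adjusted p = 0.0637) and without withdrawal replicate 1.

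Acute phase genes fell, with 8 of 21 measured lower and none higher (11 lower adjusted over the list alone) and a median change of -0.45. Saa2, a serum amyloid protein, was 36.6-fold lower, with 8.75, 10.89 and 9.32 on the continuous arrays and 4.38 to 4.51 on the withdrawal arrays. Crp was 4.51-fold lower and Itih3 3.81-fold lower. The camera test gave adjusted p = 3.45e-06, and adjusted p = 0.340 with an estimated correlation. The array with the highest Saa2, continuous replicate 2, also carried pancreatic acinar signal, with Ctrb1 at 8.56 against 5.79 to 6.90 on the other 5 arrays. Without it 8 members were still lower, and the change of Saa2 was -4.58. Interferon response genes were lower in 2 of 11 measured (4 lower adjusted over the list alone), Ifit1 (-1.27, SE 0.21) and Irf7 (-0.86, SE 0.15), with a list median of -0.30. For this list camera gave adjusted p = 0.0208 for that list, adjusted p = 0.303 with an estimated correlation, 0.0821 without continuous replicate 1 and 0.0711 without withdrawal replicate 3.

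Of 13 measured hepatocyte secreted proteins and identity factors, 3 fell and none rose (the same counts adjusted over the list alone), with a median of -0.07. Thrombin precursor F2 (-0.99), coagulation factor F9 (-1.21) and the transcription factor Cebpa (-0.58) fell. Cebpa kept its call, among left-out arrays, without continuous replicate 3 only (highest adjusted p = 0.196, without withdrawal replicate 1), and lost it with median centring (0.150). The list gave camera adjusted p = 0.0712, and passed without continuous replicate 2 (adjusted p = 0.0437), continuous replicate 3 (0.0428) or withdrawal replicate 2 (0.0245). Of 6 measured oncofetal genes 2 rose (2 higher adjusted over the list alone), with a median of 0.12 and camera adjusted p = 0.199. These were Afp (5.62 ± 0.31 to 8.94 ± 0.83, adjusted p = 3.01e-04) and Gpc3, a cell surface proteoglycan (3.77-fold, adjusted p = 1.63e-04), while Dlk1 had a change of -0.44 (adjusted p = 0.207).

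Of 15 measured circadian clock genes, 3 fell and 1 rose (5 lower and 1 higher adjusted over the list alone), with a median of -0.10 and camera adjusted p = 0.241. The repressor Nr1d1 (-2.26, SE 0.22), the clock output factor Dbp (-1.58, SE 0.18) and Bhlhe40 (-1.21) fell, and Cry1, another repressor, rose (1.12, SE 0.18). The hour of collection was not given in the sources used here. Without continuous replicate 3 the counts were 5 lower and 2 higher.

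Several of the largest changes lay outside these lists. Slc1a1, a glutamate and aspartate carrier, rose 17.8-fold, and Slc16a5, a monocarboxylate carrier family member, rose 14.8-fold and 10.5-fold on its separate probe sets. Among falls were the carboxylesterase Ces3b (30.5-fold lower), the methyltransferase Inmt (24.5-fold), the secreted glycoprotein Lrg1 (15.7-fold), the uridine phosphorylase Upp2 (14.8-fold) and the sulfotransferase Sult2a8 (14.2-fold). All 10 named rises and all 10 named falls kept their calls under each alternative tried.

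**Figure D2:**
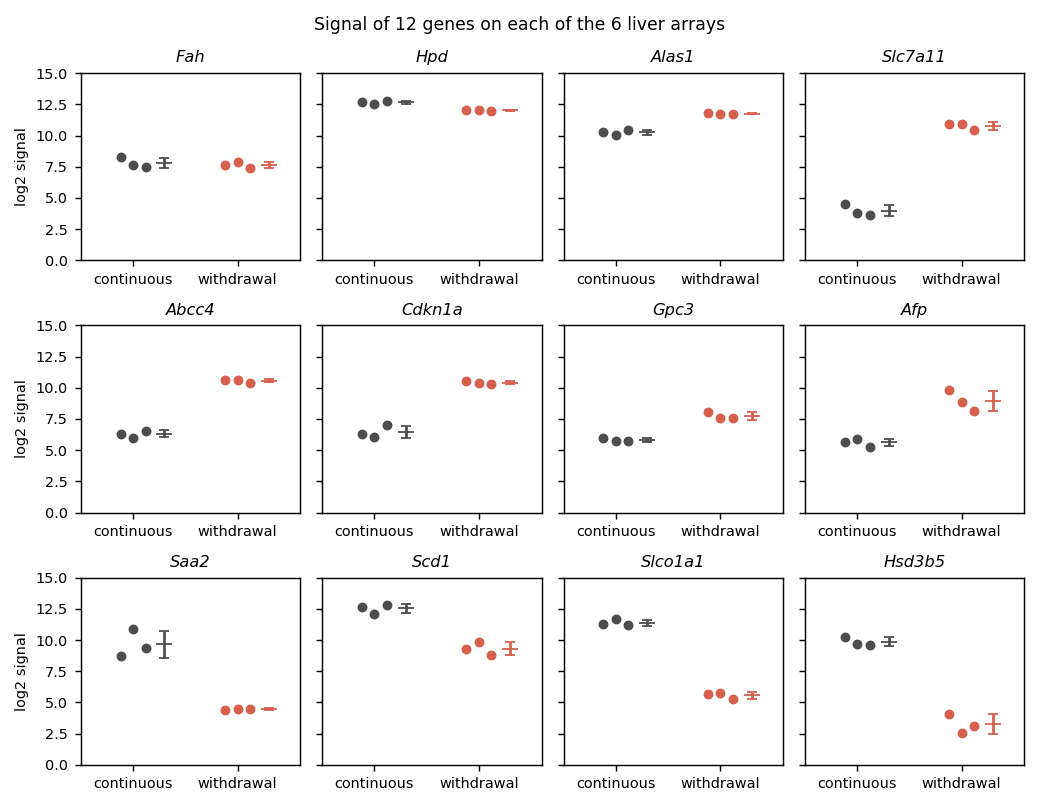
Log2 signal (vertical axis) of 12 genes on each of the 6 arrays, grouped by treatment (horizontal axis), with mean and SD beside the 3 points of each group. Slc7a11 sits near 3.99 on average with NTBC and near 10.78 after withdrawal, whereas the points for Fah overlap.

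Among markers of other liver cell types, those of the sinusoidal endothelium were higher as a list, with 3 of 14 measured past the threshold (3 higher adjusted over the list alone) and a median of 0.38. These were Clec4g (0.81, SE 0.14), Lyve1 (1.07, SE 0.27) and Gpr182 (0.83, SE 0.23). Camera gave adjusted p = 6.97e-04, and adjusted p = 0.340 with an estimated correlation. The count was 5 without continuous replicate 1 and 1 without continuous replicate 2, without any 1 withdrawal array, and with quantile normalization. Lyve1 was lost in those last cases (adjusted p up to 0.130), and Gpr182 in them and without continuous replicate 3 (up to 0.166).

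None of 11 Kupffer cell markers (median 0.16, camera adjusted p = 0.153), 17 stellate cell and matrix markers (median -0.09, mean 0.02, upward camera direction, adjusted p = 0.957) or 7 cholangiocyte markers (median -0.14, adjusted p = 0.957) passed limma's adjusted p, over all probe sets or adjusted over the list alone. Their smallest p-values belonged to C1qb (0.35, adjusted p = 0.246), Tgfb1 (0.59, adjusted p = 0.0543) and Sox9 (0.54, adjusted p = 0.0697). Without withdrawal replicate 3, 1 Kupffer marker was higher and the list passed camera (adjusted p = 0.0112). Without continuous replicate 1, 1 stellate marker was higher and 1 cholangiocyte marker lower.

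Monocyte and recruited macrophage markers had 1 of 11 lower (2 lower adjusted over the list alone), Fn1 (-0.91), which hepatocytes also express, with a median of -0.10 and camera adjusted p = 0.296. Neutrophil markers had 1 of 10 lower (2 adjusted over the list alone), Retnlg (-0.65, at or below the lower quartile of signals on all 6 arrays, where raising them to it left a 1.08-fold fall), with a median of -0.12 and camera adjusted p = 0.172. Lymphocyte markers had 1 of 13 lower (1 adjusted over the list alone), Gzmb (-0.67), with a median of -0.08 and camera adjusted p = 0.296. The Retnlg call held, among left-out arrays, without continuous replicate 1 only, and the Gzmb call without withdrawal replicate 3 only (highest adjusted p = 0.169 and 0.173, without withdrawal replicate 2). Both counts were 0 in all the other left-out cases, and with quantile normalization and median centring.

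Of 6 adipocyte markers 1 rose (1 higher adjusted over the list alone), Fabp4 (5.00-fold, adjusted p = 9.93e-04), with a median of -0.13, a mean of 0.22, a downward camera direction and adjusted p = 0.957. Adipoq and Plin1, which mark fat cells, had changes of -0.11 and -0.24 and did not pass. None of 7 pancreatic acinar markers passed, over all probe sets or adjusted over the list alone (median -0.42, camera adjusted p = 0.172). On continuous replicate 2 Cpb1 stood at 7.18 and Cpa1 at 7.26, against at most 3.78 and 5.48 elsewhere. The list passed camera without continuous replicate 1 (adjusted p = 0.0324) or continuous replicate 3 (0.0360), and gave adjusted p = 0.962 without continuous replicate 2. The only measured erythroid marker, Slc4a1, had a change of 0.23 (adjusted p = 0.368).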

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

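Leaving out each array in turn for the variance share and for the members of lists, each alternative for the lists added later, and the folds without each array or with low signals raised to the lower quartile, were chosen after seeing the data. Of the 104 genes that the rule allowed to be named, 78 passed. Of these, 67 kept their calls in every alternative fit that included them, and 11 lost them in 1 or more. The 2-fold thresholds, and list members named after their values were seen, were not part of this count. Of those members, Abcb4, Cpt1a, Ebp, Igfbp1, Mcm2, Sqle and Stard4 lost their calls in 1 or more fits, as given above. Of the 104, 0 reversed, where a change of sign counted only if the gene passed as deposited or in the alternative. Sign changes of genes that passed in neither were not counted. With array weights 5588 probe sets passed (3339 higher, 2249 lower). With a 2-fold change required, 1178 (748 and 430) passed at the adjusted p and 1215 (756 and 459) at an unadjusted p of 0.05. Median centring gave 708 lower ones. With 1 array left out the total ran from 1454 to 4210, the higher ones from 935 to 2629 and the lower ones from 519 to 1581. Calls shared with the fit as deposited had the same sign in every alternative. The weight of withdrawal replicate 1 was 3.26, against 0.545 to 1.02 for the others, and with fewer arrays there are fewer degrees of freedom.

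With the replicate number as a replicate block, 3298 probe sets passed and 90.8% of the calls were kept. Deviations of same-numbered arrays had correlations of 0.160, -0.125 and 0.217 across probe sets, and continuous replicate 1 and withdrawal replicate 2, of different numbers, reached 0.253, so the numbers were not taken to pair the samples. The block changed the call of 0 lists, against 12 passed without it.

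With an estimated correlation 0 lists passed camera. The adjusted p was then 0.104 for NRF2 targets and male-biased liver genes, 0.249 for p53 targets and bile acid synthesis and transport, 0.303 for urea cycle and amino acid catabolism and interferon response, 0.340 for integrated stress response, acute phase response and sinusoidal endothelial markers, 0.388 for lipogenesis, and 0.498 for phenylalanine and tyrosine catabolism and for fatty acid oxidation and PPARA targets. The estimated correlation allows for members of a list that vary together, but this was not its only effect. Interferon response had an estimated correlation of 0.00359, below the preset 0.01. Its unadjusted camera p still went from 0.00804 to 0.0524. A list lost in this setting is therefore not by itself a sign that its members vary together. With camera at the preset correlation, NRF2 targets ran from 3.63e-37 to 4.92e-23 and male-biased liver genes from 9.31e-20 to 3.02e-11 over the other alternatives. Both gave 4.41e-04 with fry, which compares a list with no other genes. With fry, fatty acid oxidation and PPARA targets gave 0.0509, and lists that had not passed gave 0.00115 (cytochrome P450 and other phase I enzymes), 0.0157 (hepatocyte secreted proteins and identity factors), 0.0106 (oncofetal genes), 0.0243 (circadian clock) and 0.0104 (female-biased liver genes, and monocyte and recruited macrophage markers). Without dim probe sets the integrated stress response gave 0.137 and the hepatocyte list 0.0259. Quantile normalization gave 0.0376 for cholesterol synthesis and for the hepatocyte list, and array weights 0.0483 for Kupffer cell markers. With 1 array left out the adjusted p ran from 0.0145 to 0.962 for cholesterol synthesis, from 0.0245 to 0.214 for the hepatocyte list, from 0.00683 to 0.0821 for interferon response, from 0.0112 to 0.394 for Kupffer cell markers and from 0.0324 to 0.962 for pancreatic acinar markers. The cause was not tested. The first principal component took 69.4% of the variance without dim probe sets and 54.4% to 65.5% with 1 array left out. Of probe sets with a mean log2 signal below 4, 22 were higher and 71 lower, against 794 and 446 at 8 or above; no background level is given, so how far dim signals are compressed stays unknown.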

Other observations

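Lists of heat shock, complement, coagulation, iron and heme, histone, pericentral and periportal genes, the genes named from them and the small RNA pattern were chosen after seeing the data, so their tests are not independent evidence. Camera's p for them is adjusted over these 7 lists unless another number is given. Heat shock proteins rose, with 11 of 13 measured higher and none lower (12 higher adjusted over the list alone) and a median change of 0.90. Hspa1b, an inducible HSP70, rose 13.7-fold, with 5.96, 6.13 and 7.84 on the continuous arrays and 10.27 to 10.59 on the withdrawal arrays, and the fold was 20.7 without continuous replicate 3. Hspa1a, another HSP70 gene on the list, rose 1.86-fold, from 5.03 ± 0.41 to 5.92 ± 0.29 (adjusted p = 0.0337). Transcripts of Hspa1a and Hspa1b could share probes, so their separate values are uncertain. The small chaperone Hspb1 rose 5.05-fold and Hsph1, an HSP110 chaperone, 4.17-fold. Camera gave this list adjusted p = 1.44e-12 at the preset correlation and adjusted p = 0.0356 with an estimated correlation. Adjusted together with the fixed lists, over 37 lists, the latter was 0.0853, the same as for NRF2 targets and male-biased liver genes, so its pass rests on the smaller number of lists. Among genes of iron and heme handling 7 of 14 rose and 2 fell (the same counts adjusted over the list alone). Tfrc, the transferrin receptor, rose 9.25-fold and Slc48a1, a heme carrier, 7.73-fold, while Tfr2 (-1.71) and Hamp2 (-1.78) fell. Hamp, which encodes hepcidin, had a change of 0.00 (SE 0.14), with signals of 13.76 to 13.99. The array maxima were 14.34 to 14.44, and whether changes in signals this bright are compressed was not tested. Hmox1 and Fth1 are also NRF2 targets. The histone list had 5 of 25 higher (7 higher and 2 lower adjusted over the list alone), H4c9 (3.76), H4c8 (3.55), H1f2 (1.26), H4c2 (1.04) and H4c1 (0.91). The H4 genes are near-identical in sequence, so values of single ones are uncertain, although H4c12 (0.20) did not pass. The continuous signals of H4c8, H4c1 and H4c2 lay at or below the lower quartile of each array, as did the withdrawal signals of H4c2. With such signals raised to that quartile the fold was 8.32 for H4c8, 1.40 for H4c1 and 0.924 for H4c2, so the rise of H4c2 did not hold. That count was 3 without continuous replicate 2, withdrawal replicate 1 or withdrawal replicate 2, with H1f2 and H4c2 lost (adjusted p up to 0.121 and 0.0720). Without continuous replicate 1, 1 histone gene was lower. With an estimated correlation the iron and histone lists both gave adjusted p = 0.107, and with the other scalings and the preset correlation at most 6.65e-04 and 0.00435.

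Complement and coagulation genes fell together. Of 17 measured complement genes 13 fell and 1 rose (14 and 1 adjusted over the list alone), with a median change of -1.68. The membrane attack components C8b (14.1-fold lower), C8a (6.25-fold) and C9 (4.28-fold) fell, and Mbl2, a mannose-binding lectin, rose (1.05). Of 16 coagulation genes 14 fell and none rose (15 lower adjusted over the list alone), with a median of -1.01, Hgfac being 5.44-fold and factor F7 4.55-fold lower. C6 and C8a are also male-biased list members, and F2 and F9 are on the hepatocyte list. Both lists gave adjusted p = 0.107 with an estimated correlation, and at most 3.70e-14 with the preset one under each scaling. Genes of both liver zones went both ways, with 8 of 18 pericentral genes lower and 3 higher (9 and 4 adjusted over the list alone, median -0.69) and 8 of 17 periportal genes lower and 3 higher (8 and 4 adjusted over the list alone, median -0.61). Camera gave adjusted p = 8.88e-04 and 0.0242 for them, and adjusted p = 0.198 and 0.4999 with an estimated correlation. Without withdrawal replicate 2, 1 periportal gene was higher.

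Small nucleolar RNAs were lower after withdrawal, with 26 of 73 measured genes past the threshold against 1 higher, Snora2b (1.28), and a median change of -0.51 (bootstrap interval -0.71 to -0.34). Snora30 (-2.11) and Snord118 (-1.78) were among those that fell, while the lower count was 9 without withdrawal replicate 1, 14 without withdrawal replicate 3 and 15 without continuous replicate 2, and the median then ran from -0.66 to -0.42 over the arrays left out. Array scaling alone is argued against. The central 95% of medians from 10000 random lists of like signal ran from -0.03 to 0.24. Quantile normalization left the snoRNA median at -0.59. A fall of the host genes is argued against too, for the 60 of 73 snoRNA genes with a measured host. Their own median was -0.50, while the 46 genes that hold them had a median of 0.26 (0.13 to 0.44). Hosts were assigned by position without regard to strand. The bootstrap intervals here resample genes, not arrays. A lower yield of small RNAs on the withdrawal arrays cannot be told apart from a change in snoRNA levels, since 89 other short RNA genes had a median of -0.13 (-0.18 to -0.05), between the bounds set for either answer. RNA recovery and snoRNA level may both contribute, and NTBC withdrawal stays an open and untested explanation.

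The fall of male-biased liver genes (median -2.22) is not what female mice among the withdrawal arrays would give, since the measured Y-linked genes Eif2s3y (-0.06), Kdm5d (-0.48) and Uty (-0.21) had a median of -0.21 and Xist a change of -0.05. Random lists of genes with like mean signal had a 2.5th percentile of -0.26. The match was on mean signal, which the fall itself lowers, so their genes can be dimmer than male-biased genes were with NTBC. Complement and coagulation genes had medians of -1.68 and -1.01, and the hepatocyte list one of -0.07. Whether the fall of male-biased genes is shared by other abundant liver genes is therefore undecided. A candidate explanation is weaker growth hormone and STAT5 signalling, since the STAT5 targets Igfals (-2.02, adjusted p = 3.31e-05), Socs2 (-1.42, adjusted p = 0.0354) and Cish (-0.67, adjusted p = 0.0689), none of them on the list, had a median of -1.42. That median is the value of Socs2, which stood at 8.06, 6.37 and 7.87 on continuous replicates 1 to 3. On the withdrawal arrays Socs2 ran from 5.91 to 6.11, so continuous replicate 2 lay close to them. Weaker growth hormone and STAT5 signalling stays a hypothesis, because hormone and protein levels were not analysed here. A general decline of liver function could also lower the same genes. Female-biased genes had a median of -0.16, with 2 of 10 higher and 1 lower, and the list did not pass camera (adjusted p = 0.563). Of these 10 genes, 6 had a mean log2 signal below 5 in the continuous group, where changes can be compressed.

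The 6 arrays can be divided into 3 and 3 in 10 ways, the real grouping included, so no share under 0.05 can be reached. The real grouping gave 3241 probe sets, and the highest of the other divisions gave 0. It gave 12 lists with camera at the preset correlation, and the highest of the others gave 10. In both cases 1 of the 10 divisions, the real one, reached the real value. Every other division mixes the treatments, so the treatment difference widens the spread within its groups and partly remains between them. Their counts therefore do not show what arrays without any difference would give.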
